A study of Mus musculus with 4 samples.

How the data were processed

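Spinal cord RNA from naïve control and EAE mice was profiled with TaqMan low density miRNA cards. Per the labels' protocols, total RNA was extracted with Trizol, 50 ng was reverse transcribed with pooled Megaplex primers and preamplified, and PCR ran for 40 cycles on a real-time cycler. The labels name 2 control and 2 EAE samples, each a pool of 6 mice. Nothing in the labels says whether the samples of a group came from separate pools, so the spread between EAE 1 and EAE 2 may be technical. The baseline and threshold settings and the analysis software are not given in the sources used here.

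The authors deposited raw Ct values per well with a mean Ct of U6 for each sample and block, per the column headers. They also deposited a table of linear fold changes. Per the file headers, these folds are 2 to the power of minus delta-delta Ct, with the signal of each well set against a housekeeping gene, and the column compares the average of the EAE samples with the average of the control samples. The values show that U6 was the housekeeping gene. Preamplification before the PCR can change the ratio between assays, so folds were computed only within a well. The Ct was compared across wells for the detection limits, the spread by Ct and the share of late wells, and to choose which wells to give. Those comparisons do not correct for preamplification. A Ct is a logarithmic value, so a difference in cycles was read as a log2 difference at full PCR efficiency, which was not measured. No depth exists for such data, and the Ct takes its place: a well with a late Ct starts from few molecules and has a larger error.

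The comparison of columns was made first. The differences between all pairs of columns were checked for multiples of 0.1 cycles (tolerance 2e-06 cycles). Because the control columns lay on that grid they were averaged and counted as 1 sample in the main fit. This departs from the design fixed before the data were examined, which had 2 control samples. A fit with 2 control samples is given among the alternatives. In the main setting each column was set, per block, to its mean Ct over wells with a Ct under 35 in all 4 columns. The design had planned 1 mean per column, or per card where the cards are named. The blocks were instead taken from the deposited U6 means, so the reference per block is another departure. A fit with 2 control samples and 1 mean over both blocks was not made. The 8 U6 wells were left out. The 484 remaining wells with a Ct under 35 in all columns were tested with limma (lmFit and eBayes, version 3.58.1, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment at 5%. With 2 EAE samples and 1 control sample an exact permutation test cannot give a p under 0.33, and with 2 against 2 the smallest two-sided p is 0.33 as well. Wells at least 2-fold apart with both EAE values outside the range of both control columns were counted without a p-value. Figures were drawn with matplotlib 3.10.9.

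The fit was tested on simulated data, with the real wells' Ct levels, a spread that followed the Ct as between the EAE samples, and a second control column made by adding the observed differences to the first. Over 50 simulations of 484 wells of the EAE against control comparison with no change, the fit with 1 control sample called 1.12 wells on average and at most 10. With 100 changed wells it recovered 88.5% of those changed by 4 cycles, 35.0% of those changed by 2 cycles and 6.29% of those changed by 1 cycle, and 4.74 of 47.6 calls were false on average. Recovery under this adjustment depends on how many wells change, which is not known for the data, so these shares need not hold there. The simulations had either no changed wells or 100. An absence of calls in the data therefore does not tell whether a small number of wells had large changes.

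Alternatives were another reference (the deposited U6 mean, the median of the detected wells, quantile normalisation, none, and 1 mean over both blocks), a Ct limit of 32 or 38, undetected wells set to a Ct of 40, a variance prior with a trend, the replicate number as a block, and leaving out each column. The rule for named wells, fixed with that design, took the largest differences among wells past the false discovery rate, or without any, among wells whose groups did not overlap. It was cut to 2 wells each way because the wells were used without miRNA names. For the same reason the planned lists of miRNAs of cell types, families and clusters, the reference to snoRNA controls and the restriction to mouse assays were not analysed here, and repeated wells of an assay other than U6 were not averaged.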

Results

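MicroRNA levels were measured by quantitative PCR in the spinal cord of mice with experimental autoimmune encephalomyelitis (EAE), an autoimmune inflammation of the central nervous system that serves as a model of multiple sclerosis, and in the cord of naïve mice of the same C57 background. The labels list 4 samples, 2 from control and 2 from EAE mice, and each sample pooled the cords of 6 animals. Each sample was read in 768 wells of TaqMan low density cards, in which every well holds 1 assay and gives a threshold cycle (Ct), the cycle at which fluorescence crosses a set level. A Ct 1 cycle lower corresponds to 2 times as much template at full PCR efficiency. The wells form 2 blocks of equal size, the second starting at well 385, each with its own mean Ct of U6, a small nuclear RNA used as a reference. The deposited tables number the wells and were used without assay names, so wells are identified here by number and not by miRNA.

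Detection was similar in all samples. A Ct under 35 was reached in 521 wells of control 1, 520 wells of control 2, 525 wells of EAE 1 and 528 wells of EAE 2. Some Ct was given in 572 wells of each control column, in 560 wells of EAE 1 and in 567 wells of EAE 2. The median Ct of the wells under 35 was 25.5 in control 1, 25.6 in control 2, 25.7 in EAE 1 and 25.6 in EAE 2. The precision depended on the Ct. The SD between the 2 EAE samples, after each block was set to its own mean, was 0.35 cycles over the 66 tested wells with a mean Ct under 20, 0.36 over 166 wells from 20 to 25, 0.53 over 183 wells from 25 to 30, and 1.04 over 69 wells from 30 to 35. In the last of these ranges 39.1% of wells differed by over 1 cycle between the 2 EAE samples, against 4.55% in the first.

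The 2 control columns did not differ as the other pairs of samples did. Control 2 minus control 1 was a multiple of 0.1 cycles, within 2e-06 cycles, in 570 of the 572 wells in which both had a Ct. This share was 99.7% (exact 95% interval 98.7% to 99.96%, with wells taken as independent units, although consecutive wells shared differences). Among the 5 other pairs of columns, none of the wells, at least 536 per pair, gave such a difference. Over all wells the control columns held 15 distinct differences, whereas the EAE columns held 536 in 536 wells. The most frequent differences between the control columns were -0.1 cycles in 35.3% of the wells, 0.2 cycles in 24.7% and 0.3 cycles in 16.1%, and consecutive wells shared them. In 91.2% of neighbouring wells the difference was the same, against a median of 45.4% and at most 51.6% in 10000 random orders of the wells within each block (one-sided permutation p = 0.0001, the smallest these orders can give). All wells marked undetermined in control 1 held a spreadsheet error value in control 2. The 2 control columns were therefore averaged and counted as 1 control sample in the main fit. Counts of wells without overlap or detected in one group only used both columns. The spread between control pools is not known from these data.

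**Figure D1:**
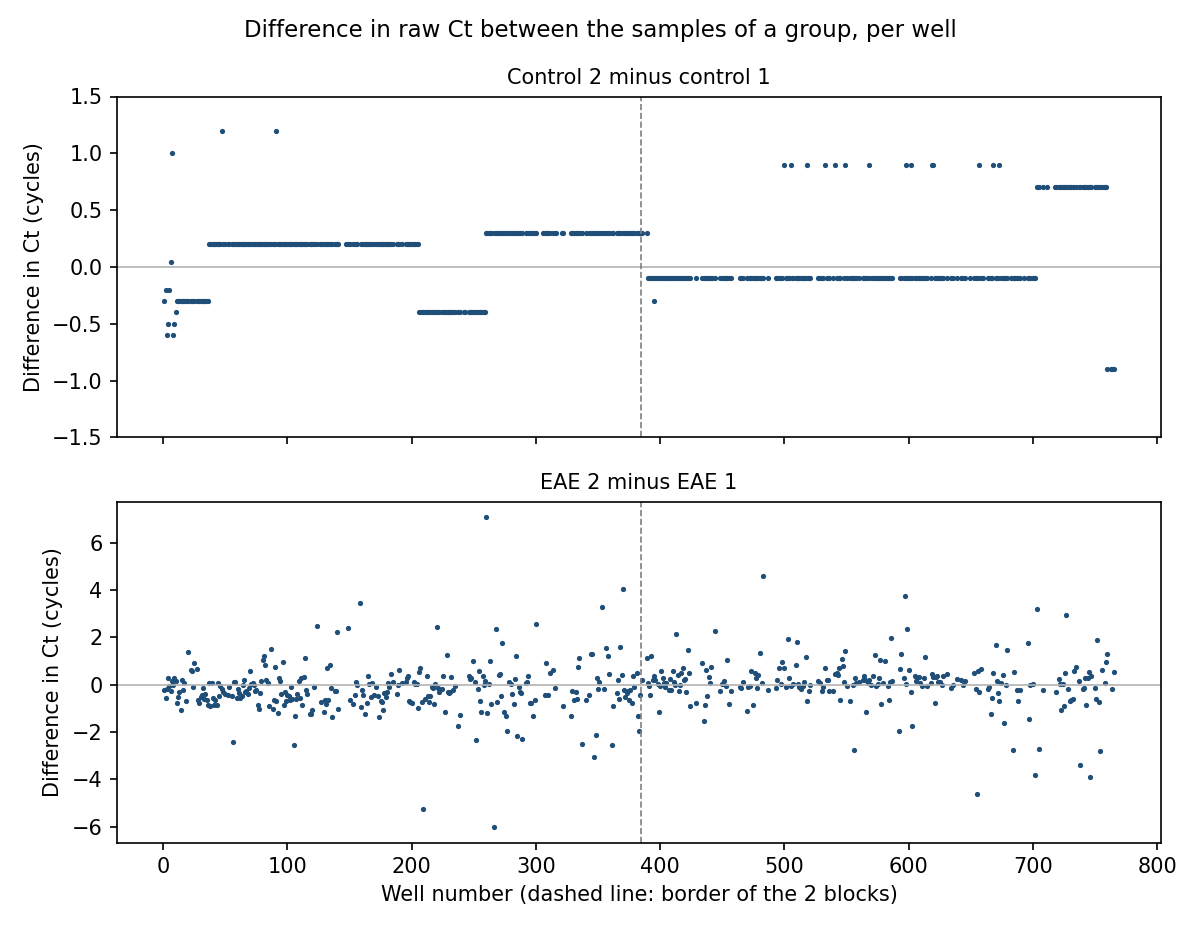
Difference in raw Ct (cycles, vertical axis) between the samples of one group against the well number (horizontal axis), with 1 point per well, for the control columns (top) and the EAE columns (bottom, on a wider scale). The control differences lie on 15 values and stay constant over long stretches of wells, while the EAE differences scatter around 0.

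The main comparison asked which miRNA assays differed between EAE and control cord. Of the 484 wells with a Ct under 35 in every column, with U6 wells left out, 119 were at least 2-fold apart with both EAE values on the same side of both control values. Of these, 61 were higher and 58 lower in EAE, under a reference that removes the average difference in each block. A mean Ct of 30 or more was found in 38 of the 119, out of 69 tested wells in that range. Another 34 had a mean Ct under 25, out of 66 tested wells under 20 and 166 from 20 to 25. In 13 of the 119 the EAE samples lay further apart than the difference itself. At 4-fold or more the count was 29 wells higher and 7 lower. None of the 484 wells passed a 5% false discovery rate (limma with Benjamini-Hochberg adjustment, 1 control sample against 2 EAE samples, lowest adjusted p = 0.15), and 79 had an unadjusted p under 0.05 where 24.2 are expected at a nominal 5%. In simulations of this fit without any change, 6.10% of wells had such a p. The fit had 1 residual degree of freedom, from the EAE samples, and assumes that control pools vary as EAE pools do. With the control columns counted as 2 samples, 105 wells passed (56 higher, 49 lower), where simulations of that fit without any change called 16.9 on average. With a trended variance prior 6 wells passed (4 higher, 2 lower). With undetected wells set to a Ct of 40, 15 passed (3 higher, 12 lower), and with 1 mean over both blocks 11 passed, all higher. Other settings are given below. By chance, both EAE values lie on one side of a single control value in 66.7% of unchanged wells. This holds if the EAE values differ from each other as much as from the control. With EAE samples from the same pool the share would be higher, and the labels leave that open. Both EAE values lay on one side in 395 wells (81.6%) against control 1 alone and in 385 wells (79.5%) against control 2 alone. In 333 wells (68.8%) they lay on one side of both columns, to which the 66.7% does not apply.

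The largest differences among the tested wells are given as values, since none passed the test with 1 control sample. Well 289, in the first block, was higher in EAE by 5.14 on the log2 scale (SE 1.05, limma adjusted p = 0.24), with a Ct of 30.7 in EAE 1 and 28.4 in EAE 2 against 34.2 in control 1. Well 359, also in the first block, was higher by 4.03 (SE 0.46, limma adjusted p = 0.15), with a Ct of 31.1 ± 0.33 (SD, n = 2) in EAE against 34.7 in the control. Well 441, in the second block, had a log2 difference of -3.56 (SE 0.44, limma adjusted p = 0.16), with a Ct of 34.6 ± 0.53 (SD, n = 2) in EAE and 31.3 in the control. Well 566, in the second block, had a log2 difference of -3.55 (SE 0.69, limma adjusted p = 0.24). Its Ct was 24.2 ± 0.83 (SD, n = 2) in EAE and 20.9 in the control, which makes it the only one of these 4 wells with a Ct under 28 in all samples. In wells 289, 359 and 441 the group with the higher Ct lay close to the limit of 35. Well 441 had a Ct of 34.98 in EAE 2. The control values in this paragraph are the mean of both control columns unless a column is named. The 4 differences kept their sign under each alternative in which the well was tested. The wells were chosen for large differences and the alternatives use the same Ct values, so this adds no support. With the control columns counted as 2 samples all 4 wells passed (limma adjusted p from 0.0012 to 0.0053), as they did with the replicate number as a block in that fit (0.0050 to 0.0094), and well 359 passed with 1 mean over both blocks (0.035). The fits with 2 control samples, with or without the block, take the spread between the control columns as replicate error. In simulations without any change, the fit without the block gave an unadjusted limma p under 0.05 in 21.5% of wells. With U6 as the reference the log2 difference of wells 441 and 566 was -4.69.

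**Figure D2:**
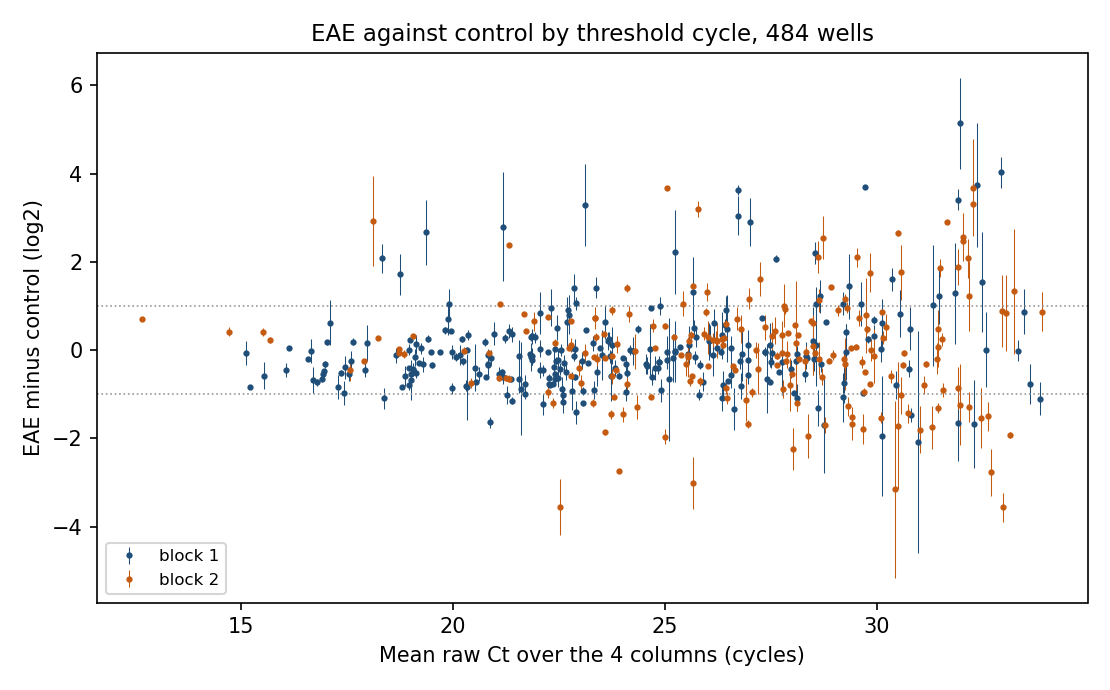
Difference between EAE and control (log2, vertical axis) against the mean raw Ct of the 4 columns (cycles, horizontal axis) for the 484 tested wells. Points are means of the 2 EAE samples minus the control, bars reach to the 2 EAE samples, and dotted lines mark 2-fold. The bars widen above a Ct of 30, where the SD between EAE samples was 1.04 cycles.

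The level and the direction of the differences depended on the reference. The deposited fold changes, which use U6, put 74.7% of wells below 1, with a median fold of 0.66 in the authors' deposited table. That median was 0.805 in the first block and 0.437 in the second block of the authors' deposited table. With U6 as the reference, 190 wells were at least 2-fold apart without overlap, 35 higher and the others lower in EAE, against 61 higher and 58 lower with the mean of the detected wells. The median log2 difference with U6 was -0.36 in the first block and -1.17 in the second block, against -0.16 and -0.03 with the mean of the detected wells. The latter reference removes the average difference of the tested wells in each block, so its small block medians largely follow from the setting. Without any reference the block medians were -0.55 in the first block and 0.26 in the second block. At 4-fold or more, 16 wells were higher and 44 lower with U6, so the excess of higher wells seen at this size with the mean of the detected wells turned to an excess of lower wells. The wells that were at least 4-fold apart without overlap under each of the 6 references tried numbered 15 higher and 6 lower in EAE. Of these, 9 higher and 3 lower had a mean Ct under 30, and in 8 higher and 2 lower the EAE samples lay under 1 cycle apart.

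**Figure D3:**
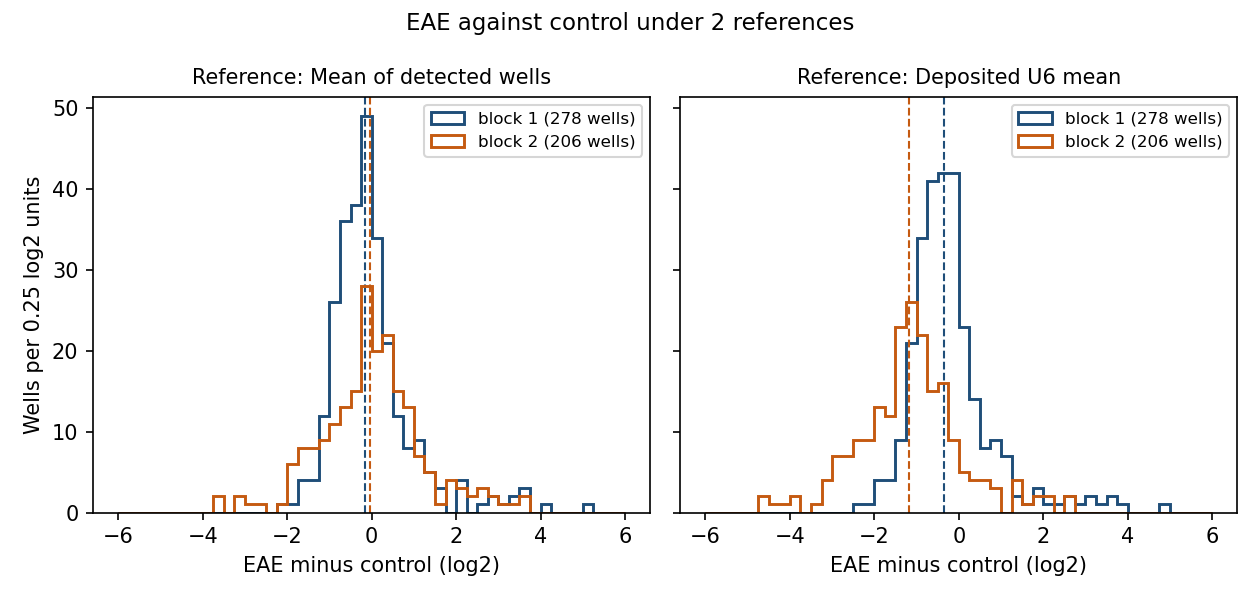
Number of wells per 0.25 log2 units (vertical axis) by difference between EAE and control (log2, horizontal axis) in block 1 (278 of the 484 wells) and block 2 (the others), with the mean of the detected wells (left) or the deposited U6 mean (right) as the reference. Dashed lines are the block medians, which lie at -0.16 and -0.03 on the left and at -0.36 and -1.17 on the right. The reference on the left removes the average difference in each block by construction.

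U6 itself differed between the groups by another amount in each block. In the first block the mean Ct of the 4 U6 wells (wells 11, 12, 35 and 36) was 15.4 in EAE and 15.0 in the control, a difference of 0.35 cycles, which was 0.71 cycles in EAE 1 and -0.0041 cycles in EAE 2. In the second block (wells 395, 396, 419 and 420) it was 15.2 in EAE and 16.6 in the control, a difference of -1.38 cycles, which was -1.51 cycles in EAE 1 and -1.25 cycles in EAE 2. The SD of the 4 U6 wells within a column was between 0.026 and 0.18 cycles. The U6 wells were found as the 4 positions whose mean gives the deposited U6 mean of control 1 in both blocks. The deposited U6 mean of control 2 was 0.29 cycles above the mean of its own 4 wells in the first block and 0.1 cycles above it in the second block.

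A Ct under 35 was reached in both samples of one group and in neither column of the other in 28 wells, 16 in EAE and 12 in the control. At a Ct limit of 38 the split was 6 in EAE and 13 in the control, and without EAE replicate 1 the count was 53 wells. For these 28 wells only a lower bound of the fold can be given, with the other group set at a Ct of 35 and each block set to the mean of its detected wells. Of the wells detected in EAE, the one with the lowest mean Ct in EAE had a Ct of 28.5 ± 1.06 (SD, n = 2) in EAE and 37.9 in the control, at least 123-fold higher in EAE, or at least 66.8-fold from EAE 2 alone and 225-fold from EAE 1 alone. The one with the next lowest had a Ct of 28.7 ± 0.070 (SD, n = 2) in EAE and 36.9 in the control, at least 62.4-fold higher. Of the wells detected in the control, the one with the lowest mean Ct there had a Ct of 30.9 in the control and 37.1 ± 0.81 (SD, n = 2) in EAE, at least 20.7-fold lower in EAE. The bound was at least 4-fold in 10 of the 16 wells detected in EAE and in 5 of the 12 detected in the control. In 2 wells of each kind the other group had no Ct at all.

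The authors' deposited table gives a fold change for 533 wells, from 0.00575 to 1017. Of these, 531 were recovered from the deposited Ct and U6 columns within 1e-05 on the log2 scale, as the mean of the linear EAE values over the mean of the linear control values. The other 2 wells, the last of the second block, have a fold of 0.342 and 0.0297 in the authors' deposited table and no Ct in any column. The deposited folds and the differences computed with the mean of the detected wells had the same sign in 389 of 484 wells. This share was 80.4% (Wilson 95% interval 76.6% to 83.7%). The interval takes wells as independent units, although both values come from the same Ct and share a reference within a block. Across wells, which are not independent replicates, their correlation on the log2 scale was r = 0.91 (Spearman's rho = 0.83).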

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

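These settings were added after seeing the data: 1 mean over both blocks, and U6 with both control columns as separate samples. The fit with both control columns as separate samples, as the design had them, became an alternative only then. The reference per block was also chosen after the deposited U6 means of the blocks were seen. The count of wells past the 5% false discovery rate (limma, 0 in the main setting) was also 0 with U6, the median, quantile normalisation or no reference, with a Ct limit of 32 or 38, and without either control column. It was 15 (3 higher, 12 lower) with undetected wells at a Ct of 40, 6 (4 higher, 2 lower) with a trended prior and 11 (all higher) with 1 mean over both blocks. It was 105 (56 higher, 49 lower) with both control columns as separate samples, 167 (27 higher, 140 lower) when U6 was used as well, and 63 (38 higher, 25 lower) with the replicate number as a block and without U6. The difference between samples 1 and 2 correlated at -0.062 between the groups (484 wells), which says little on pairing, as that of the controls lies on a grid of 0.1 cycles. These 3 counts take the spread between the control columns as replicate error. For the fit that gave 105, without U6 or a block, 50 simulations without any change called 16.9 of 484 wells on average and up to 55. With 100 changed wells, 37.7 of 114 calls of that fit were false on average. Without EAE replicate 1 or 2 no residual degree of freedom was left for a test.

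The number of wells 2-fold apart without overlap (119) was 190 with U6 and within 1.5 times of 119 in all other settings. Of the 119, 93 were also among the 190, all in the same direction. The share of wells with the sign of the deposited fold (80.4%) was 97.7% with U6, 83.7% with the median, 83.9% with a Ct limit of 38, 73.1% without a reference, 73.3% with 1 mean over both blocks, and 73.3% to 81.4% with 1 column left out. The 28 wells detected in one group only became 29 to 53 with 1 column left out, the 53 being without EAE replicate 1, and at a Ct limit of 38 the split of 16 in EAE and 12 in the control turned to 6 and 13. None of the 4 named wells changed the sign of its difference, which their choice by size made likely. The main split of 61 wells 2-fold higher and 58 lower turned to an excess of lower wells in several settings. Among these were U6 (35 higher), the median (54 and 63), no reference (69 and 89) and a Ct limit of 38 (67 and 75). It also turned with undetected wells at 40 (77 and 79) and 1 mean over both blocks (74 and 75). The same held without control replicate 1 (65 and 68) or 2 (58 and 59). Late wells were less precise (SD of 1.04 cycles at a Ct of 30 to 35, 0.35 under 20). The cause of other differences was not tested.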

Other observations

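The tests on the control columns, on the level of U6 RNA and on the Ct of the brighter group were chosen after the values were seen. The tests on the amount of material per block and on late wells were fixed before.

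The 2 control columns differ by multiples of 0.1 cycles. Separate measurements of 2 samples cannot account for this, since 99.7% of wells lay on that grid and none did in any of the 5 other pairs of columns. A second reading of the same cards with another threshold is argued against by the same 570 wells, because a moved threshold shifts a Ct by an amount that depends on the curve of the well and not by a round step. The data are consistent with control 2 having been computed in a spreadsheet from control 1: neighbouring wells shared the same difference in 91.2% of cases, and 100% of the undetermined wells of control 1 hold a spreadsheet error in control 2. The deposited U6 mean of control 2 in the first block, 15.164931, also equals the mean of the first 2 U6 wells of control 1, and the deposited U6 means of EAE 1 and EAE 2 in that block are means of the same 2 wells. The purpose of such a step is not known from the files, and a mistake made when the table was assembled stays open.

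The U6 reference moves the fold changes of the 2 blocks apart. Both blocks should hold the same RNA of a sample, so another level of U6 RNA in EAE cord would shift U6 alike in both. The U6 difference between EAE and control instead moved by -1.73 cycles from the first block to the second (-2.22 in EAE 1, -1.25 in EAE 2). Most of this lay in the control, whose U6 mean moved by 1.53 cycles, against -0.20 cycles in EAE. The values of EAE 1 and EAE 2 share that control, so they are not separate observations of the shift. The SD of at most 0.18 cycles between U6 wells covers repeat wells of a column and not the spread between cards. The shift argues against another U6 level as the only cause, but not against one that adds to an effect of the cards. Unequal material on the cards of 1 block may contribute: the median difference over the other wells moved between the blocks by -0.82 cycles, 47.2% of the shift of U6, just under the 50% set in advance for this explanation. By sample this median moved by -1.02 cycles in EAE 1, under 50% of its U6 shift, and by -0.70 cycles in EAE 2, over 50%. These values by sample share the control as well. Unequal material cannot be told apart from real differences between the miRNAs of the 2 blocks, because the blocks hold different assays. It bears on the 140 wells called lower when U6 and both control columns were used.

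Very large deposited fold changes were found at late cycles more often than smaller ones. Of the 87 wells with a deposited fold of at least 4 or at most 0.25 (U6 wells left out), 26 had a Ct of 35 or more in some column (29.9%), against 13 of 436 other wells (2.98%), which is 10.0 times the share (two-sided Fisher's exact test, p = 2.5e-13). A large change raises the highest Ct by itself, so this share was also taken in the group with the lower Ct. There a rise in EAE works the other way, while a fall in EAE, as in 58 of the 87 wells, leaves the Ct of the control unmoved. In that group 44.8% of these wells and 11.2% of the others had a Ct of 30 or more. This is 3.99 times the share (p = 5.5e-12, two-sided Fisher's exact test, with wells taken as independent units as in the first test). Both tests pooled the blocks, and none was made within a block. The median fold in the authors' deposited table was 0.805 in the first block and 0.437 in the second. A difference in Ct between the blocks could therefore also contribute to these shares. Few template molecules are only a candidate source of part of these folds, while 61 of the 87 wells had a Ct under 35 in every column. The U6 reference is another: of the 87 folds 29 were higher and 58 lower in EAE, and the wells at least 4-fold lower without overlap numbered 44 with U6 and 7 with the mean of the detected wells. The 4 highest folds of the authors' deposited table, 105 to 1017, each set EAE values with a mean Ct from 28.5 to 30.1 against control values of 36.9 to 38.4. The SD between the EAE samples of these wells was 0.070 to 2.32 cycles (n = 2). The largest was in the well with the fold of 419, at a Ct of 28.0 in EAE 1 and 31.2 in EAE 2.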
